A study of Mus musculus with 8 samples.

How the data were processed

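Per the labels' protocols, posterior joint capsules were flash frozen, RNA was extracted with Trizol, and directional libraries were made from 200 ng of total RNA after depletion of ribosomal RNA. They were sequenced with paired 150-nt reads on a DNBSEQ-G400 instrument. The protocol text names Trimmomatic 0.38 and mapping to transcripts of the human build hg38 with Bowtie2 within RSEM. The submitters' processing notes name Trimmomatic 0.36, Bowtie2, RSEM and edgeR with the mouse build mm10. These statements conflict, and the symbols in the deposited table are those of mouse genes. Versions of Bowtie2, RSEM and edgeR, the transcript annotation and whether counting used the strand are not given in the sources used here, so genes that overlap on opposite strands are uncertain.

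The authors deposited 1 signal value per gene and library, a normalised read count, for 16464 genes in 8 libraries. Each value divided by the smallest step of its library was whole within 0.01 for 100% of genes, and the steps matched read counts scaled to a common total of the listed genes and adjusted by edgeR's trimmed mean of M values within 0.0003%. Whole reads were recovered from these steps, 20826744 in naive and 27307862 in cast libraries in all. The smallest sum of reads of a gene was 8, so genes with fewer reads had been left out before deposit. Symbols were matched to GENCODE release M21 (GRCm38, the same assembly as mm10) for coordinates, transcript length and GC content, which 15795 genes (95.9%) had. Ctgf had no coordinates there.

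Values were taken to log2 after adding 1, and genes with a mean of at least 0.5 were kept, which left 15120. Groups were compared with limma-trend, with Benjamini-Hochberg adjustment at 0.05. Gene lists with at least 5 tested members, 41 in number, were compared with camera at a preset correlation of 0.01, and the mean level of each list per library with two-sided exact permutation tests over 70 assignments. A further list, of 13 mitochondrially encoded genes, had 0 members in the table and was not tested. Group labels and lists, filter, tests, the rule for named genes and the alternatives, except those named as chosen after seeing the data, were set before the data were examined.

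Named genes were the 12 with the largest rise and the 12 with the largest fall on the log2 scale among genes past the threshold whose groups did not overlap, whose higher mean was at least 5 times the filter and whose symbol was not a predicted or clone name. To these came the 3 members with the smallest p of each list past camera or with at least 0.25 of its tested members past the threshold, and a fixed panel of 12 genes whatever their test. Some genes that this rule or a count would name are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

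The alternatives set in advance were pseudocounts of 0.5 and 5, no filter and a filter 5 times stricter, median-of-ratios scaling, quantile normalisation, and scaling without muscle, erythroid and marrow genes. Others were limma without a trend, array weights, the level of muscle genes as a covariate, replicate number as a block, each library left out in turn, limma treat against a fold of 1.5, edgeR quasi-likelihood and DESeq2 on recovered reads, camera with estimated correlations, and fry. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. In simulated data of the same size, limma called 16% of 2-fold and 71% of 4-fold changes and 3 of 14895 unchanged genes, and 0 of 15120 genes where no change was simulated. Fewer genes were changed there than were called in the real data, so these shares need not hold for the real data. Camera called the list raised 1.5-fold and 0 of 40 random lists. Genes were drawn independently there, so false calls of camera from correlated genes could not have shown. Raw sequence reads were not used here.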

Results

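RNA was sequenced from the posterior capsule of the knee joint of male C57BL/6 mice that were 10 weeks old. Naive capsules formed 1 group of 4 libraries. The other 4 libraries came from mice whose knee had been held at 140 degrees in a cast for 2 weeks, from 8 weeks of age. The deposited table lists 16464 genes by symbol. Its values were normalised read counts, namely counts scaled to a common total of the listed genes and adjusted by trimmed means. In each library every value was a whole multiple, within 0.01, of the value of 1 read, so that whole reads could be recovered. The naive libraries held 6805349, 6479420, 6038095 and 1503880 recovered reads, and the cast libraries held 5956148, 6607967, 7362492 and 7381255. Naive replicate 4 was thus the shallowest library, and 2264 genes were at 0 in it against 487 to 608 in the other naive libraries and 330 to 364 in the cast libraries. Its correlation with naive replicates 1 to 3 across genes was 0.882 to 0.897, against 0.979 to 0.982 among those 3 (log2 values, genes not being independent replicates). Deposited totals were 1010462 ± 31656 in naive and 990048 ± 9881 in cast libraries (mean ± SD, n = 4 each; two-sided exact permutation p = 0.314). The 10 most abundant genes took 12.7 ± 1.37% of the naive and 9.46 ± 1.02% of the cast values (n = 4 each; two-sided exact permutation p = 0.0286, the smallest these groups allow).

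The comparison of cast with naive capsules asks how gene expression in the joint capsule changed with immobility of the knee. Of 15120 genes tested with limma, 984 rose and 826 fell after casting (Benjamini-Hochberg adjusted p at most 0.05), which is 11.97% of the genes tested. By camera, a test of gene lists, at a preset correlation, lists of neutrophil, cytokine, T cell and natural killer cell, erythroid, protease and cell division genes were higher in cast capsules, and those of muscle, fat storage, immediate early and basement membrane genes lower. With estimated correlations 0 of 41 lists passed (smallest adjusted p = 0.153), and from 8 of 26 (proteases) to 8 of 12 members (erythroid genes) of these lists passed the gene test in the direction of the list. The rise with the highest log2 fold change among genes with separate groups was that of Mmp13, a collagenase, from 4.75 ± 5.57 to 1507 ± 1266 (log2 fold change 7.97, adjusted p = 0.000422). The deepest fall was that of Retnla, a gene of alternatively activated macrophages, from 155 ± 10.3 to 6.41 ± 10.5 (log2 fold change -5.41, adjusted p = 0.00266). Values are means of normalised read counts ± SD with n = 4 per group, fold changes are cast minus naive on the log2(value + 1) scale, and adjusted p values of genes are from limma with the Benjamini-Hochberg method. Of the 1810 changed genes, 800 rose and 548 fell at least 2-fold. In 3104 genes (20.53%) all 4 libraries of one group lay above all 4 of the other, against 2.86% expected by chance, and 1726 of these were among the 1810. Leaving out 1 library gave 1011 changed genes without naive replicate 2, 1045 without naive replicate 3, 1139 without cast replicate 2 and 920 without cast replicate 3. No label says that the libraries came from separate mice, so the p values measure only the spread between these samples.

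**Figure D1:**
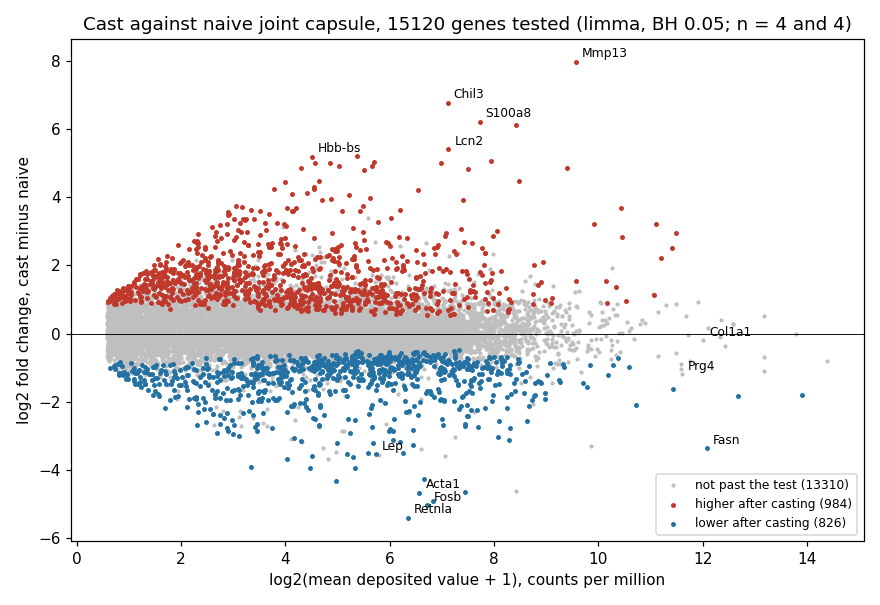
Log2 fold change of each of 15120 tested genes (cast minus naive, vertical axis) against log2 of its mean normalised read count plus 1 (horizontal axis), with 984 genes higher and 826 lower after casting in colour (limma, n = 4 per group). Mmp13 lies highest at 7.97 and Retnla lowest among the coloured genes at -5.41.

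Genes of neutrophils and their marrow precursors rose most as a group. Of 19 tested members of this list, 12 rose and 7 did not pass the test (13 higher adjusted over the list alone), with a median log2 fold change of 3.39. The list passed camera, a test against all other genes (adjusted p = 1.05e-11; adjusted p = 0.364 with an estimated correlation). Chil3, a chitinase-like protein of myeloid cells (chromosome 3, 106147554 to 106167564, minus strand, build GRCm38), rose from 1.41 ± 1.04 to 273 ± 128 (log2 fold change 6.76, adjusted p = 0.000131). S100a8, which pairs with S100a9 to form calprotectin (chromosome 3, 90668978 to 90670035, plus strand), rose from 3.62 ± 2.58 to 417 ± 415 (log2 fold change 6.21, adjusted p = 0.000371). Csf3r, the receptor of granulocyte colony-stimulating factor, rose from 10.3 ± 5.402 to 135 ± 45.3 (log2 fold change 3.63, adjusted p = 0.000347). Cd177, a neutrophil surface protein, was 0.837 ± 0.891 in naive and 101 ± 121 in cast capsules (log2 fold change 5.04, adjusted p = 0.00488). Ngp and Ltf, genes of secondary granules, had log2 fold changes of 5.06 (adjusted p = 0.0263) and 4.99 (adjusted p = 0.0189). The call of Ngp was lost without naive replicate 1, naive replicate 3, cast replicate 1 or cast replicate 2 (adjusted p = 0.0616, 0.0737, 0.0706 and 0.0515), and that of Ltf without naive replicate 3 or cast replicate 1 (adjusted p = 0.0549 and 0.0519). With Ms4a3, which was at 0 in all naive libraries, at its lower bound, the median of the list was 3.63.

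Primary granule genes of marrow precursors, chosen after their values were seen, separated the cast libraries. Mpo, the myeloperoxidase gene, was 55.05 and 144 in cast replicates 1 and 2, 0.273 and 0.133 in cast replicates 3 and 4, and at most 3.23 in the naive libraries. Elane, neutrophil elastase, was 10.7 and 43.01 in the first pair and 0.136 and 0.267 in the other. Ctsg, cathepsin G, was 7.58 and 18.7 against 0 and 0.267. Jchain, a plasma cell gene with 2 naive reads in all, was 4.78 and 10.04 against 0 in cast replicates 3 and 4, a cast to naive ratio of pooled reads of 36.6 (95% counting interval 9.86 to 307). None of these 4 genes passed the test (adjusted p = 0.382, 0.223, 0.406 and 0.258). Prtn3, a further primary granule gene of the neutrophil list, did pass and was among its 12 members that rose. Without cast replicates 1 and 2, an alternative chosen after seeing the data, S100a8 and Chil3 had log2 fold changes of 5.48 and 6.17 (adjusted p = 0.00492 and 0.00421). Ngp and Ltf were 2.79 and 3.08 in that fit (adjusted p = 0.118 and 0.0921), which called 715 genes.

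Inflammatory cytokines and targets of the transcription factor NF-kB rose as a group. Of 29 tested members 12 rose and 17 did not pass (19 higher adjusted over the list alone), with a median of 1.37. The list passed camera (adjusted p = 2.75e-09; adjusted p = 0.203 with an estimated correlation). Lcn2, an iron-sequestering protein shared with the neutrophil list, rose from 4.74 ± 0.828 to 272 ± 171 (log2 fold change 5.41, adjusted p = 9.19e-05). Cxcl12, a chemokine of stromal cells, rose from 347 ± 94.6 to 2444 ± 445 (log2 fold change 2.83, adjusted p = 0.000299). Il1b, which encodes interleukin 1 beta (chromosome 2, 129364570 to 129371139, minus strand), rose from 1.45 ± 0.864 to 31.5 ± 21.5 (log2 fold change 3.59, adjusted p = 0.000972). Saa3, an acute-phase protein, rose from 0.248 ± 0.496 to 45.2 ± 34.6 (log2 fold change 5.003, adjusted p = 0.000383). Cxcl5, a neutrophil-attracting chemokine, was 0.199 ± 0.307 in naive and 55.6 ± 43.7 in cast capsules (log2 fold change 4.99, adjusted p = 0.00361). Its reads pooled over each group, 2 of them naive, gave a ratio of 613 (95% counting interval 169 to 5070), and the group means gave 279. Il6 was 0.151 ± 0.301 in naive and 2.77 ± 3.39 in cast capsules and did not pass (adjusted p = 0.116). S100a8, S100a9 and Lcn2 stood in both this list and the neutrophil list. Intervals and floors cover counting error only.

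Matrix proteases were higher, and lists of bone cells did not pass camera with all 8 libraries. Of 26 proteases and inhibitors, 8 rose, 1 fell and 17 did not pass (12 higher and 2 lower adjusted over the list alone). The list passed camera (median 0.74, adjusted p = 0.000799; adjusted p = 0.364 with an estimated correlation). With the level of muscle genes, which was also low in naive replicate 4, as a covariate its adjusted p was 0.0894. Mmp13 (chromosome 9, 7272514 to 7283331, plus strand) has the value given above. Mmp3, stromelysin 1, rose from 37.6 ± 20.4 to 1302 ± 851 (log2 fold change 4.86, adjusted p = 0.00112). Mmp8, the neutrophil collagenase, rose from 0.803 ± 0.887 to 80.1 ± 69.9 (log2 fold change 5.20, adjusted p = 0.000889). Timp1, an inhibitor of these proteases, was 29.7 ± 15.2 in naive and 93.4 ± 53.5 in cast capsules without passing (adjusted p = 0.0516). Without naive replicate 4, Timp1 passed with a log2 fold change of 1.84 (adjusted p = 0.02245). Among 12 osteoclast genes, Mmp9 and Tnfsf11 rose and Tnfrsf11b fell (6 higher and 2 lower adjusted over the list alone; median 0.85), and the list did not pass camera (adjusted p = 0.0630; adjusted p = 0.714 with an estimated correlation) but did in 3 alternatives, such as without cast replicate 4 (median 1.08, adjusted p = 0.00224). Mmp9 stood in the neutrophil and protease lists too. Tnfsf11, the osteoclast-inducing ligand, rose from 0.356 ± 0.237 to 29.4 ± 11.6 (log2 fold change 4.43, adjusted p = 8.25e-05). Tnfrsf11b, its decoy receptor, was 6.89 ± 2.29 in naive and 2.07 ± 1.32 in cast capsules (log2 fold change -1.41, adjusted p = 0.0278), and its call was lost without naive replicates 1, 2 or 3 or cast replicates 2 or 4 (adjusted p = 0.0685, 0.0796, 0.0554, 0.0790 and 0.0635). Of 14 osteoblast and osteocyte genes, Runx2, Ibsp and Spp1 rose and Bglap, Bglap2 and Smpd3 fell (3 higher and 3 lower adjusted over the list alone; median 0.31; adjusted p = 0.814 by camera). Spp1, osteopontin, rose from 9.67 ± 3.75 to 118 ± 63.8 (log2 fold change 3.39, adjusted p = 0.00120).

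T cell and natural killer cell genes rose from low levels, and B cell genes did not pass the test. Of 16 T cell and natural killer cell genes 8 rose and 8 did not pass (12 higher adjusted over the list alone), with a median of 1.01 (adjusted p = 1.90e-07 by camera; adjusted p = 0.153 with an estimated correlation). Cd4, a T helper cell co-receptor also found on myeloid cells, rose from 1.87 ± 1.45 to 15.5 ± 4.83 (log2 fold change 2.61, adjusted p = 0.00304). Cd3e, of the T cell receptor complex, rose from 0.0817 ± 0.0943 to 2.55 ± 0.506 (log2 fold change 1.71, adjusted p = 0.00126). Its reads pooled over each group, 2 of them naive, gave a ratio of 26.7 (95% counting interval 7.12 to 225). The level of this list in naive replicate 4 was 0.535 against 0.775 to 0.8105 in the other naive libraries (mean log2). Of 12 B cell and plasma cell genes, limma called 0, with 1 at an unadjusted p under 0.05, and edgeR called 0 and DESeq2 1 (median 0.24; adjusted p = 0.796 by camera). Among 25 macrophage genes Ms4a7, Clec4e and Chil3 rose and Folr2, a marker of resident macrophages, fell (4 higher and 2 lower adjusted over the list alone; median 0.26). That list had adjusted p = 0.0692 by camera and 0.00415 without naive replicate 4, where 7 members rose and 2 fell, and passed in 8 other alternatives. Of 12 mast cell genes, Fcer1a and Hdc rose (2 higher adjusted over the list alone; median 0.64, adjusted p = 0.0469 by camera; adjusted p = 0.636 with an estimated correlation). The mast cell call was lost without naive replicate 2, naive replicate 3 or cast replicate 4 (adjusted p = 0.0689, 0.146 and 0.212). It was lost in 11 of 24 alternatives in all, among them the muscle covariate (adjusted p = 0.325), both pseudocounts (0.0508 and 0.0539), the stricter filter (0.0731), thinned libraries (0.0904), the GC trend removed (0.0596) and fry (0.174).

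Complement and coagulation genes shifted upward, with 4 of 21 members higher, 1 lower and 16 not past the test (5 higher and 1 lower adjusted over the list alone). The list passed camera (median 0.62, adjusted p = 0.00530; adjusted p = 0.394 with an estimated correlation), but not with the muscle covariate (adjusted p = 0.310). Cfi, complement factor I, rose from 0.264 ± 0.527 to 12.9 ± 3.74 (log2 fold change 3.49, adjusted p = 0.000356). F5, coagulation factor V, rose from 3.24 ± 0.564 to 35.1 ± 10.1 (log2 fold change 3.05, adjusted p = 0.000195). C6 and Masp1 of the complement cascade also rose, and Thbd, the thrombomodulin gene, fell. Of 26 antigen presentation and interferon genes, H2-Aa rose and Oas1a fell, and limma called 0 adjusted over the list alone, with 6 at an unadjusted p under 0.05 and 2 called by edgeR and 4 by DESeq2 over all genes (median 0.25; adjusted p = 0.814 by camera). Its level was 5.99 in naive replicate 4 and 5.18 to 5.297 in the other naive libraries. With the muscle covariate this list had a median of -0.60 and an adjusted p of 0.0111, which is the opposite direction. It passed upward in 3 alternatives: array weights (0.34, adjusted p = 0.0455), without naive replicate 4 and cast replicate 1 (0.42, adjusted p = 0.00321) and without cast replicates 1 and 2 (0.52, adjusted p = 0.0241).

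Red cell genes rose, and haemoglobin was higher in each cast library than in any naive library. Of 12 erythroid genes 8 rose and 4 did not pass (8 higher adjusted over the list alone), with a median of 2.31 (adjusted p = 2.87e-05 by camera; adjusted p = 0.364 with an estimated correlation). The 6 haemoglobin genes summed to 15240, 8197, 29220 and 5939 in cast replicates 1 to 4 and to 1743, 2321, 1693 and 2900 in naive replicates 1 to 4. Hba-a1, an alpha globin (chromosome 11, 32283511 to 32284465, plus strand), rose from 564 ± 140 to 5159 ± 4074 (log2 fold change 2.94, adjusted p = 0.00455). Hbb-bs, a beta globin, had 0 reads in all naive libraries and a value of 43.6 ± 33.8 in cast capsules (adjusted p = 0.000281). By reads pooled over each group, rather than by these means, it was at least 316-fold higher against a floor of 3 reads over the naive group. That bound covers counting error only, and not reads assigned to other beta globin genes. Hbb-b1, a beta globin chosen after its value was seen, was 726 ± 271 in naive and 4695 ± 3221 in cast capsules (log2 fold change 2.51, adjusted p = 0.0103). Its adjusted p was 0.0668 without cast replicates 1 and 2. The median of the list was the same with Hbb-bs at its bound. Beta globin genes share reads: Hbb-bt and Hbb-b2, chosen after their values were seen, had identical values in all 8 libraries (log2 fold change 2.36, adjusted p = 0.0142), so the split of reads among these paralogs is uncertain. Without cast replicates 1 and 2 these 2 genes did not pass (adjusted p = 0.0882). Haemoglobin reads per read of S100a8 and S100a9 were 22.2, 3.02, 77.5 and 10.3 in cast replicates 1 to 4 and 203, 130, 427 and 204 in naive replicates 1 to 4.

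**Figure D2:**
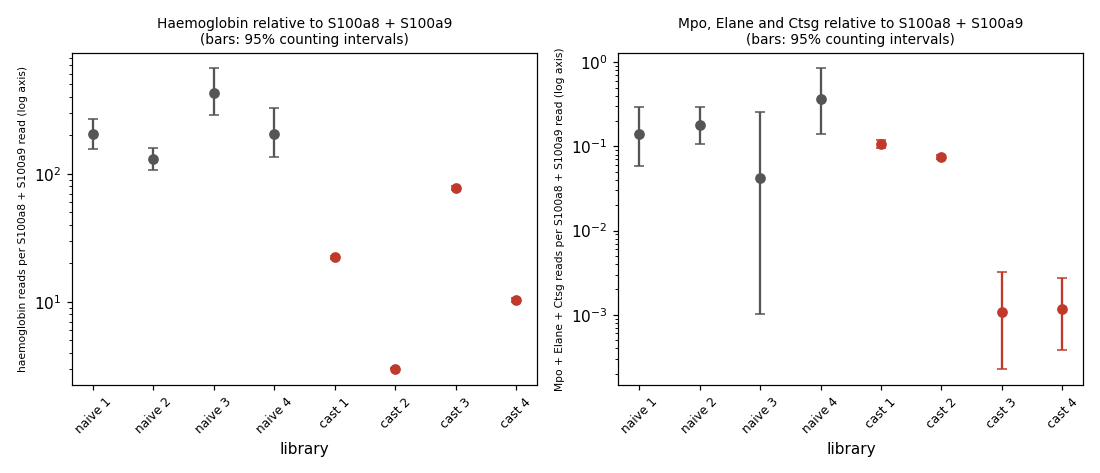
Reads of 6 haemoglobin genes (left) and of Mpo, Elane and Ctsg (right) per read of S100a8 and S100a9 in each library, on log axes, with 95% counting intervals as bars. The haemoglobin ratio ran from 3.02 to 77.5 among the 4 cast libraries, and the ratio of Mpo, Elane and Ctsg from 0.00108 to 0.107.

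Cell division genes rose together, and ribosomal protein genes shifted slightly upward. Of 29 cell cycle genes 16 rose and 13 did not pass (26 higher adjusted over the list alone), with a median of 1.69 (adjusted p = 8.02e-11 by camera; adjusted p = 0.366 with an estimated correlation). The mean log2 level of the list was 3.24, 2.73, 2.10 and 1.78 in naive replicates 1 to 4. It was 4.07, 4.44, 4.28 and 3.26 in cast replicates 1 to 4, so cast replicate 4 was close to naive replicate 1. Bub1b, a mitotic checkpoint kinase, rose from 4.31 ± 1.397 to 17.2 ± 3.99978 (log2 fold change 1.79, adjusted p = 0.00352). Aurka, the Aurora A kinase, rose from 1.31 ± 0.866 to 5.62 ± 1.75 (log2 fold change 1.56, adjusted p = 0.0157). Birc5, or survivin, was 1.403 ± 1.11 in naive and 7.75 ± 3.09 in cast capsules (log2 fold change 1.87, adjusted p = 0.0152), with an adjusted p of 0.0525 without cast replicate 3. Of 35 cytosolic ribosomal protein genes Rps6 rose (median 0.72), and limma called 0 adjusted over the list alone, with 16 at an unadjusted p under 0.05 and 2 called by edgeR and 10 by DESeq2 over all genes. The list passed camera (adjusted p = 1.76e-06; adjusted p = 0.612 with an estimated correlation), and its adjusted p was 0.794 with the muscle covariate and 0.137 by fry. Without naive replicate 4, 20 of the 35 ribosomal genes rose. Rps6 was 300 ± 62.1 in naive and 552 ± 139 in cast capsules (log2 fold change 0.87, adjusted p = 0.0429), and its call was lost without any one of naive replicates 1 to 3 or cast replicates 2 to 4, where its adjusted p was 0.0811, 0.120, 0.0576, 0.0603, 0.126 and 0.0976.

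**Figure D3:**
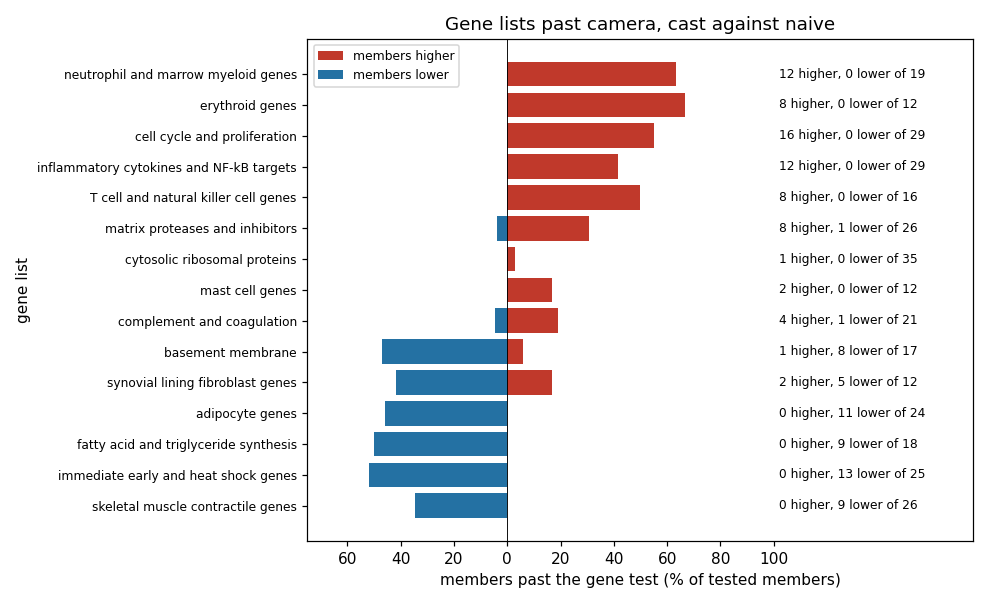
Share of tested members higher (right of 0) and lower (left of 0) after casting in the 15 gene lists past camera, ordered by median log2 fold change, with the counts at the right. Neutrophil and marrow myeloid genes had 12 of 19 members higher and skeletal muscle contractile genes 9 of 26 lower.

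Fat storage genes fell. Of 24 adipocyte genes 11 fell and 13 did not pass (14 lower adjusted over the list alone), with a median of -1.18 (adjusted p = 1.35e-07 by camera; adjusted p = 0.364 with an estimated correlation). Of 18 genes of fatty acid and triglyceride synthesis 9 fell and 9 did not pass (10 lower adjusted over the list alone), with a median of -1.20 (adjusted p = 1.35e-07 by camera; adjusted p = 0.203 with an estimated correlation). Dgat2, an enzyme of triglyceride assembly, fell from 465 ± 139 to 73.6 ± 59.4 (log2 fold change -3.04, adjusted p = 0.0133). Adrb3, the adrenergic receptor of fat cells, fell from 55.6 ± 16.3 to 5.89 ± 3.37 (log2 fold change -3.22, adjusted p = 0.00304). Me1, malic enzyme 1, fell from 305 ± 66.97 to 58.04 ± 22.5 (log2 fold change -2.43, adjusted p = 0.00128). Pck1, which feeds glycerol synthesis in fat cells, fell from 373 ± 166 to 81.4 ± 33.9 (log2 fold change -2.19, adjusted p = 0.00546). Pnpla3, a lipid droplet protein, fell from 217 ± 101 to 10.1 ± 11.5 (log2 fold change -4.92, adjusted p = 0.00444). Lep, the leptin gene (chromosome 6, 29060220 to 29073877, plus strand), fell from 93.4 ± 47.2 to 10.9 ± 9.51 (log2 fold change -3.54, adjusted p = 0.0285), and its call was lost without naive replicate 2, naive replicate 3 or cast replicate 3 (adjusted p = 0.0613, 0.0779 and 0.0750). Adipoq and Fabp4, abundant fat cell genes named after their values were seen, were 537 ± 116 in naive and 350 ± 195 in cast capsules and 994 ± 118 in naive and 1559 ± 776 in cast capsules and did not pass (adjusted p = 0.253 and 0.315). The level of the synthesis list was 8.05 in naive replicate 4 and 7.80 to 7.84 in the other naive libraries.

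Skeletal muscle genes fell, and they were also low in 1 naive library. Of 26 contractile genes 9 fell and 17 did not pass (22 lower adjusted over the list alone), with a median of -3.06 (adjusted p = 4.55e-11 by camera; adjusted p = 0.394 with an estimated correlation; adjusted p = 0.0504 by fry). The mean log2 level of the list was 6.15, 5.74 and 6.52 in naive replicates 1 to 3, 2.79 in naive replicate 4, and 3.84, 1.55, 1.66 and 2.70 in the cast libraries. As a covariate this level therefore also marked naive replicate 4 within the naive group, so fits with it do not adjust for muscle content alone. Without naive replicate 4, 24 members fell, with a median of -4.26. Myl1, a fast-fibre myosin light chain, fell from 89.1 ± 54.9 to 4.89 ± 1.28 (log2 fold change -3.50, adjusted p = 0.0111). Acta1, skeletal actin, was 182 ± 123 in naive and 6.34 ± 8.14 in cast capsules (log2 fold change -4.66, adjusted p = 0.0146), its groups overlapped, and its adjusted p was 0.0508 without cast replicate 3. Among 18 genes of denervation, atrophy and regeneration, 4 rose, Runx1, Gadd45a and Ampd3 among them, and Foxo1 fell (4 higher and 1 lower adjusted over the list alone). That list had a median of -0.25 but a mean of 0.16, and did not pass camera (adjusted p = 0.975, upward). Runx1, a transcription factor of blood and denervated muscle, rose from 104 ± 43.99 to 330 ± 36.98 (log2 fold change 1.72, adjusted p = 0.00339).

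Immediate early and heat shock genes fell. Of 25 members 13 fell and 12 did not pass (17 lower adjusted over the list alone), with a median of -1.30 (adjusted p = 4.62e-10 by camera; adjusted p = 0.203 with an estimated correlation). Fosb, an AP-1 subunit (chromosome 7, 19302696 to 19310051, minus strand), fell from 205 ± 188 to 3.66 ± 2.41 (log2 fold change -5.03, adjusted p = 0.00337). Klf4, a Kruppel-like transcription factor, fell from 299 ± 36.5 to 56.4 ± 16.9 (log2 fold change -2.42, adjusted p = 0.000299). Hspa1a, an inducible Hsp70 chaperone, fell from 40.4 ± 8.69 to 8.28 ± 1.36 (log2 fold change -2.15, adjusted p = 0.000371); Hspa1b is a near-identical paralog, so the split of reads between them is uncertain. Atf3, a stress transcription factor, fell from 66.5 ± 44.4 to 3.93 ± 0.828 (log2 fold change -3.52, adjusted p = 0.00185). Of 12 tendon and ligament genes Egr1, Egr2 and Cilp2 fell (1 higher and 4 lower adjusted over the list alone; median -0.06; adjusted p = 0.213 by camera). Egr1 and Egr2 are immediate early genes as well as regulators of tendon cells. Cilp2, a cartilage and tendon matrix protein, fell from 41.1 ± 34.1 to 1.35 ± 0.8500 (log2 fold change -3.95, adjusted p = 0.00111).

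The basement membrane and synovial lining lists were lower by camera, with members changed in both directions, while the main fibrillar collagens did not pass the gene test. Of 17 basement membrane genes 8 fell, Lamb1 rose and 8 did not pass (9 lower and 1 higher adjusted over the list alone), with a median of -0.45 (adjusted p = 1.65e-05 by camera; adjusted p = 0.364 with an estimated correlation). The median was -0.69 without cast replicate 1. The call of Lamb1 was lost in 7 of the 8 fits without 1 library (adjusted p from 0.0540 to 0.0974). Lamb2, laminin beta 2, fell from 772 ± 87.3 to 231 ± 34.2 (log2 fold change -1.74, adjusted p = 0.000570). Col4a5, a collagen IV chain, fell from 154 ± 45.4 to 36.5 ± 5.55 (log2 fold change -2.01, adjusted p = 0.000910). Of 12 genes of synovial lining fibroblasts 5 fell, namely Clic5, Tspan15, Hbegf, Col22a1 and Itga6, and Vcam1 and Pdpn rose (6 lower and 2 higher adjusted over the list alone). The list passed camera (median -0.68, adjusted p = 0.00701; adjusted p = 0.364 with an estimated correlation). Its adjusted p was 0.0503 without cast replicate 1, 0.0506 without naive replicate 4 as well, 0.0546 with no filter and 0.113 with the muscle covariate, and its median was -1.06 without naive replicate 4. Clic5, an intracellular channel protein, fell from 557 ± 179 to 63.5 ± 22.1 (log2 fold change -3.13, adjusted p = 0.000398). Hbegf, an EGF-like growth factor, fell from 157 ± 29.4 to 15.8 ± 5.896 (log2 fold change -3.28, adjusted p = 0.000198). Vcam1, an adhesion molecule induced in inflammation and named after its value was seen, rose from 32.7 ± 14.9 to 164 ± 72.1 (log2 fold change 2.32, adjusted p = 0.00580). Prg4, the lubricin gene, was 4312 ± 1334 in naive and 1914 ± 829 in cast capsules and did not pass (adjusted p = 0.0706). Without naive replicate 4, Prg4 passed with a log2 fold change of -1.455 (adjusted p = 0.0178).

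Of 27 genes of fibrillar collagens and their processing, Col12a1 and Lox rose and Col5a3, Loxl2, Loxl4, P4ha1 and P4ha2 fell (2 higher and 6 lower adjusted over the list alone; median -0.35; adjusted p = 0.0636 by camera). The list passed in 5 alternatives, such as without cast replicates 1 and 2 (median -0.60, adjusted p = 0.00391). Col1a1 (chromosome 11, 94936224 to 94953042, plus strand) was 4068 ± 1857 in naive and 4154 ± 3114 in cast capsules (log2 fold change -0.20, adjusted p = 0.867), and Col3a1 was 14186 ± 5798 in naive and 14153 ± 5253 in cast capsules (log2 fold change -0.00, adjusted p = 0.997). Lox, which cross-links collagen, rose from 168 ± 49.2 to 696 ± 310 (log2 fold change 2.02, adjusted p = 0.00493). Of 33 proteoglycans, glycoproteins and elastic fibre genes, Lum, Efemp1, Efemp2, Emilin1 and Cthrc1 rose and Prelp, Fn1, Tnxb, Thbs3 and Mfap5 fell (8 higher and 7 lower adjusted over the list alone). That list had a median of 0.29 and a mean of 0.31, but camera gave a downward direction without passing (adjusted p = 0.975). Tnxb, tenascin X, fell from 2723 ± 554 to 667 ± 303 (log2 fold change -2.10, adjusted p = 0.00338). Fn1, fibronectin, was 23602 ± 6355 in naive and 7218 ± 3619 in cast capsules (log2 fold change -1.81, adjusted p = 0.0390), and its call was lost without naive replicate 1, 2 or 3 or cast replicate 3 or 4 (adjusted p = 0.0921, 0.0987, 0.0723, 0.122 and 0.0815).

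Fibrosis and cartilage lists did not pass camera with all 8 libraries. In a fixed panel of 12 genes of matrix, fibrosis, inflammation and hypoxia, Mmp13 and Il1b rose and Ctgf and Fn1 fell; 5 were higher and 3 lower adjusted over the list alone, Timp1, Il6, Hif1a and Prg4 being the others. Of 24 genes of TGF-beta signalling and myofibroblasts, Cdh11 rose (1 higher adjusted over the list alone; median 0.06; adjusted p = 0.796). Tgfb1 was 63.6 ± 14.9 in naive and 69.8 ± 15.2 in cast capsules (adjusted p = 0.742) and Acta2, smooth muscle actin, 227 ± 103 in naive and 287 ± 29.4 in cast capsules (adjusted p = 0.368). Without naive replicate 4, Acta2 passed with a log2 fold change of 0.70 (adjusted p = 0.0201). Of 13 targets of the YAP and TEAD regulators, Gadd45b rose and Ctgf, Amotl2, Axl and Ptpn14 fell (1 higher and 4 lower adjusted over the list alone; median -0.34; adjusted p = 0.0643). Ctgf, a matricellular growth factor, was 668 ± 190 in naive and 207 ± 120 in cast capsules (log2 fold change -1.82, adjusted p = 0.0182), and its call was lost without naive replicate 2, naive replicate 3 or cast replicate 3 (adjusted p = 0.0571, 0.0546 and 0.0591). Of 17 cartilage genes, Col27a1, Matn3 and Pth1r rose and Sox5, Sox6, Col2a1, Chad and Cytl1 fell (3 higher and 5 lower adjusted over the list alone; median -0.15; adjusted p = 0.205). Chad, chondroadherin, fell from 38.1 ± 16.6 to 6.13 ± 3.33 (log2 fold change -2.47, adjusted p = 0.00283). Of 14 hyaluronan genes, Cemip rose and Has1 and Hyal1 fell (2 higher and 5 lower adjusted over the list alone; median -0.15; adjusted p = 0.208). Hif1a, a hypoxia regulator, was 127 ± 80.1 in naive and 357 ± 87.1 in cast capsules (adjusted p = 0.0934) and passed without naive replicate 4, at a log2 fold change of 1.12 (adjusted p = 0.00881). Without cast replicates 1 and 2 the YAP and TEAD list and the cartilage list passed (median -0.51, adjusted p = 0.00498, and -0.42, adjusted p = 0.0403). The YAP and TEAD list also passed in 3 other alternatives, and the hyaluronan list by fry (adjusted p = 0.00539). Members named by their count in these and the other lists, without values, were chosen after their values were seen. Of the 8 fits without 1 library, the calls of Bglap2, Cdkn1a, Efemp1, Itga6 and Mt1 were lost in 7, and those of Bnip3l, Cry1, Emilin1, Igfbp5, Oas1a, Pdpn, Scn7a, Sox6 and Thbd in 6. Calls were lost in 5 fits for Amotl2, Bglap, Col5a3, Cytl1, Dusp1, Gsta4, Gstm1, H2-Aa, Hdc, Hyal1, P4ha2 and Pth1r. They were lost in 1 to 4 fits for Adm, Angptl4, Cthrc1, Loxl2, Col12a1, Efemp2, Egr1, Ibsp, Phlda3, Foxo1, Loxl4, P4ha1, Folr2, Lmnb1, Lum, Matn3 and Mfap5.

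Lists of Wnt and BMP, hormone, pain, nerve, hypoxia and senescence genes did not pass camera with all 8 libraries either. Of 33 Wnt and BMP genes, Wnt5b and Sfrp1 rose and 7 fell, Wnt10b and Bmp6 among them (3 higher and 8 lower adjusted over the list alone; median -0.22; adjusted p = 0.0626). The list passed in 4 alternatives, such as without naive replicate 1 (median -0.43, adjusted p = 0.0116). Of 24 growth hormone, IGF and glucocorticoid genes, Igfbp2, Igfbp4, Mt1 and Mt2 rose and Igfbp5, Igfbp6, Cdkn1a, Dusp1 and Errfi1 fell (5 higher and 5 lower adjusted over the list alone; adjusted p = 0.975). That list had a median of 0.16 and a mean of 0.09 against a downward camera direction. Of 17 pain and neurotrophic genes, Calca, Tacr1 and Ptger4 rose and Csf1 and Ntn1 fell (5 higher and 2 lower adjusted over the list alone; median 0.28; adjusted p = 0.448). The call of Calca was lost in 7 of the 8 fits without 1 library (adjusted p from 0.0502 to 0.0999). Tacr1, the substance P receptor, rose from 6.701 ± 4.69 to 30.7 ± 13.1 (log2 fold change 2.14, adjusted p = 0.0109). Of 21 Schwann cell and nerve genes, Scn7a rose and S100b and Egr2 fell (1 higher and 3 lower adjusted over the list alone; median 0.15, mean -0.05; adjusted p = 0.530). Of 29 hypoxia and glycolysis genes, Bnip3l, Adm and Angptl4 rose and Hk2, Pfkm, Egln1 and P4ha1 fell (3 higher and 5 lower adjusted over the list alone; adjusted p = 0.796), with a median of 0.11 against a downward camera direction. Of 18 senescence and p53 genes, Lmnb1 rose and Cdkn1a, Phlda3 and Igfbp5 fell (1 higher and 3 lower adjusted over the list alone; median -0.04; adjusted p = 0.660).

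Of 24 antioxidant and NRF2 targets, Mt1 and Mt2 rose and Gsta4 and Gstm1 fell (2 higher and 2 lower adjusted over the list alone; adjusted p = 0.814 by camera), with a median of 0.07 against a downward direction. Of 24 unfolded protein response genes Atf3 fell (1 lower adjusted over the list alone; median 0.13, mean -0.01; adjusted p = 0.944). Of 19 clock genes Cry1 rose and Nr1d1 fell (1 higher and 1 lower adjusted over the list alone; median -0.28; adjusted p = 0.159). Of 26 endothelial genes Selp, P-selectin, rose (1 higher adjusted over the list alone; median 0.11; adjusted p = 0.796). Of 16 mural and smooth muscle genes Cspg4 fell (1 higher and 1 lower adjusted over the list alone; median 0.05, mean -0.03; adjusted p = 0.796). Of 5 keratinocyte genes Sbsn fell (1 lower adjusted over the list alone; median 0.25; adjusted p = 0.975, downward). Of 33 nuclear genes of oxidative phosphorylation limma called 0, with 0 at an unadjusted p under 0.05, and edgeR and DESeq2 each called 0 (median 0.06; adjusted p = 0.814). The list passed without naive replicate 4 and cast replicate 1 (median 0.29, adjusted p = 0.00623) and without cast replicates 1 and 2 (median 0.30, adjusted p = 0.0326).

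Of the 41 lists 15 passed camera with its preset correlation of 0.01, 9 upward and 6 downward. With correlations estimated per list camera passed 0 lists, with 4 at an unadjusted p under 0.05 and a smallest adjusted p of 0.153, and fry passed 14. The mean level of each list per library was also compared by two-sided exact permutation tests with n = 4 per group. There 0 lists passed the adjustment (smallest adjusted p = 0.0732), where at least 24 at the smallest p would be needed for any to pass. In that test 16 had the smallest exact p these groups allow, 0.0286, and 12 of the 16 were among the 15 past camera.

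The deviation of naive replicate 4 from the other naive libraries followed the GC content of transcripts. Across 14527 genes, its deviation from naive replicates 1 to 3 had a Spearman rho of 0.628 with transcript GC content, and the other libraries had values from -0.302 to 0.318 (genes are not independent replicates). Among the 7392 of these genes with a mean of at least 20 in naive replicates 1 to 3, the median difference of naive replicate 4 from the other naive libraries was -1.89 (log2) for genes in the lowest GC decile and 0.46 in the highest. Aspn, asporin, named after its value was seen, was 1.94 in that library. Its log2 fold change was 0.44 with all libraries and -1.08 without it, and it did not pass the test in either fit (adjusted p = 0.859 and 0.161).

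**Figure D4:**
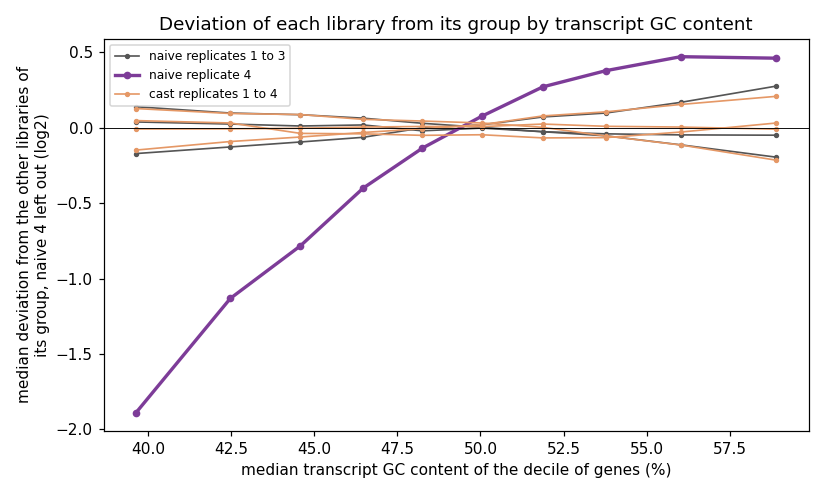
Median deviation of each library from the other libraries of its group (log2, naive replicate 4 left out of the reference; vertical axis) in deciles by transcript GC content (percent; horizontal axis) of 7392 genes with a mean of at least 20 in naive replicates 1 to 3. Naive replicate 4 runs from -1.89 in the lowest to 0.46 in the highest decile, and the other 7 libraries stay between -0.22 and 0.28.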

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

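Tests of blood and bone marrow for neutrophil and erythroid genes were chosen after the result was seen, and were then set aside. They set the spread between single libraries against counting error, used genes chosen for that spread, or rested on B cell and plasma cell genes (median 0.24 against 3.39 for neutrophil genes), of which Ebf1 and Xbp1 were high and Cd79a low in both groups. These 3 genes, and Mpo, Elane and Ctsg, were chosen after their values were seen. In 336 groups of 4 libraries, 33 held a library far from its 3 fellows, judged by its gap to the nearest as a share of the range. At a rate of 1 in 20 groups chance would give 16.8. That rate was not checked for values off the log scale or at the floor, such as those of Cfi, Il6 and Saa3. Of the 33 flagged groups, 10 were flagged for naive replicate 4.

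Naive replicate 4 had 1503880 recovered reads against 6038095 to 6805349 and 2264 genes at 0 against 487 to 608. By the rule of gaps its mean log2 level was apart in 4 gene lists: T cell and natural killer cell genes (0.535 against 0.775 to 0.811), antigen presentation and interferon genes (5.99 against 5.18 to 5.30), fatty acid and triglyceride synthesis (8.05 against 7.80 to 7.84), and senescence and p53 targets (4.67 against 4.86 to 4.90). Skeletal muscle contractile genes were further off there (2.79 against 5.74 to 6.52) but did not meet that rule, as the other naive libraries varied more. Naive replicate 4 was also apart from the other naive libraries in Tppp3 (516 against 257 to 299), Mup2 (89.3 against 7.58 to 11.6), Chad (62.7 against 26.3 to 31.8) and Acvr1c (66.6 against 178 to 198).

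A candidate explanation for the distance of naive replicate 4 is a trend with transcript GC content: its deviation had a Spearman rho of 0.628 across genes, and the next largest of the other libraries was 0.318. The tables argue against lower depth as the whole cause of its genes at 0. Naive replicates 1 to 3 thinned to its reads had at most 1683 genes at 0 in 60 draws, below its 2264. Before thinning they had 487 to 608, so lower depth may account for part of its genes at 0. The draws were compared by genes at 0 only, which leaves its other differences undecided for depth. For transcript length, rho was -0.244 against -0.240 to 0.316 in the other libraries, just past their lower end, which leaves that explanation undecided. A difference in the tissue itself stays open, because its muscle genes were low as well, and no biological explanation was tested.

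Among the other naive libraries, the list level of Schwann cell and nerve genes was 3.42 in naive replicate 1 against 3.69 to 3.72, and that of antioxidant and NRF2 targets was 6.46 in naive replicate 3 against 6.60 to 6.63. Cilp2 was 92.1 in naive replicate 1 against 20.1 to 26.8 in the others, Mmp3 68.1 against 24.5 to 30.2, and Igfbp4 583 against 758 to 790. Cfi and Il6 were 1.06 and 0.603 in naive replicate 1 and 0 in the other naive libraries, and Saa3 was 0.992 in naive replicate 3 and 0 in the others.

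Among the cast libraries, cast replicate 1 was high for muscle denervation, atrophy and regeneration genes (4.42 against 3.58 to 3.69), Lox (1158 against 496 to 585) and Aspn (275 against 48.5 to 83.2), and low for hypoxia and glycolysis genes (6.10 against 6.35 to 6.39). Cast replicate 2 was high for clock genes (5.51 against 5.25 to 5.28), S100a8 (1035 against 142 to 250), S100a9 (1681 against 235 to 436), Tnxb (1120 against 483 to 551), Egr2 (5.09 against 2.47 to 2.59) and Smpd3 (27.9 against 9.72 to 12.1). Cast replicate 3 was high for Tnfsf11 (46.6 against 22.1 to 25.7) and Il1b (63.4 against 16.1 to 23.7). Cast replicate 4 was high for Retnla (22.1 against 0.136 to 2.31) and Fcer1a (21.5 against 4.12 to 5.84) and low for immediate early and heat shock genes (4.49 against 4.97 to 5.07).

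Neutrophil and erythroid genes were higher in the cast libraries. Haemoglobin reads per read of S100a8 and S100a9 ran from 3.02 to 77.5 among the cast libraries and from 130 to 427 among the naive libraries. Mpo, Elane and Ctsg together had 445 and 1373 reads in cast replicates 1 and 2, 3 and 5 in cast replicates 3 and 4, and 1 to 20 in each naive library. Blood, bone marrow and casting itself stay open for this pattern, in whole or in part.

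Adipocyte genes were lower in the cast libraries. To argue against fewer fat cells as the whole cause, at least 3 abundant members had to change relative to Adipoq. Of 20 such members 3 did: Lep by -2.77 ± 0.513 and Dgat2 by -2.27 ± 0.476 downward, and Fabp4 by 1.32 ± 0.361 upward (log2 ± SE, limma adjusted p = 0.00135, 0.00231 and 0.0148). Without naive replicate 3 there were 2 changed members, short of that rule, and with the GC trend removed 4. The test takes Adipoq as constant per fat cell and the members as specific to fat cells, which was not checked. With all libraries the rule was met only with Fabp4 counted, so its outcome rests on Fabp4 being specific to fat cells. The test argues against this cause only under these assumptions. A lower share of fat cells may account for part of the fall, and a change within fat cells after casting is a candidate explanation for Lep and Dgat2.

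The real split into cast and naive called 1810 genes, the highest of the others called 1, and 1 of 35 splits, the real one itself, gave as many. That is the best rank these splits allow. The other splits mix cast and naive libraries, so any difference between the groups adds to their spread and keeps their calls few. This test therefore cannot exclude chance, and it cannot tell casting from another difference that goes with the groups.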

How the results depend on the processing

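The alternatives chosen after seeing the data were those without naive replicate 4 and cast replicate 1, without cast replicates 1 and 2, with libraries thinned to equal reads, and with the GC trend removed (with and without the replicate block), and library totals from recovered reads. Against 1810 changed genes, array weights gave 3985 and DESeq2 2754; the muscle covariate gave 4305 (66.85% higher, 1246 shared with the 1810). Limma treat gave 329 by its construction. Leaving out naive replicate 4 with cast replicate 1 gave 3275, leaving out cast replicates 1 and 2 gave 715, and leaving out 1 library gave 920 to 2672 (2672 without naive replicate 4, 1760 shared). For these the cause was not tested. The replicate block gave 1371 (1251 shared), edgeR 2045 and thinned libraries 1291. Deviations of libraries from their group had correlations of 0.0797, 0.0353, -0.0571 and -0.0214 between like replicate numbers. No label says whether the numbers pair the libraries, and these values cannot settle it. The 15 lists became 0 with estimated correlations and 14 to 18 without 1 library; list levels passed 0 lists in each fit, which groups of this size nearly fix and which shows no stability. Cast minus naive totals ran from -32982 to -8804 without 1 library. The antigen presentation list reversed under the muscle covariate (median -0.60). Aspn, which did not pass with all libraries, ran from -1.59 without naive replicate 4 and cast replicate 1, a reversal (adjusted p = 0.00209), to 4.67 with the muscle covariate (adjusted p = 0.00664), and at most 1.03 without 1 library. Within the naive group the muscle level set naive replicate 4 apart (2.79 against 5.74 to 6.52). Aspn (1.94 against 155 to 237) and the antigen presentation list (5.99 against 5.18 to 5.30) were apart there too. Fits with this covariate thus do not separate muscle content from that library, and the cause was not tested. The higher share was 54.36% with all libraries, 44.78% after quantile normalisation and 44.45% with the GC trend removed. The median of all genes was 0.0674, 0.105 when scaled without muscle, erythroid and marrow genes, and 0.106 with the muscle covariate. Of 165 changed genes followed through the alternatives, 106 kept their call whichever 1 library was left out and 59 lost it at least once. Depth and group size limit what can be seen. In simulated data of this size 16% of 2-fold changes were called. There 14895 of 15120 genes were unchanged, which makes the adjustment stricter than with 1810 calls, so that share need not hold here.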

Other observations

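The grouping of genes by shared symbol stem was chosen after the result was seen. It gave 246 families of at least 8 tested genes. Histone genes rose in 40 of 64 members, with a median log2 fold change of 1.44 (camera adjusted p = 2.88e-17, and adjusted p = 0.880 with an estimated correlation). Hist1h3c, a histone H3 gene, rose from 9.56 ± 7.03 to 50.3 ± 20.7 (log2 fold change 2.42, adjusted p = 0.0114), but did not pass without cast replicates 1 and 2 (adjusted p = 0.0929). Hist2h3c2 was 11.1 ± 11.8 in naive and 65.6 ± 31.4 in cast capsules (log2 fold change 3.09, adjusted p = 0.0408), and its call was lost without naive replicate 2 or any 1 cast library (adjusted p = 0.0661, 0.0611, 0.109, 0.115 and 0.0708). Histone genes are near-identical copies, so reads shared among them leave single members and the count of members that rose uncertain.

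Serpina genes rose in 6 of 9 members (camera adjusted p = 8.03e-05; adjusted p = 0.849 with an estimated correlation). All 6 were Serpina3 genes, namely Serpina3f, Serpina3g, Serpina3h, Serpina3i, Serpina3m and Serpina3n. These are similar paralogs, so the split of reads among them and the count of members that rose are uncertain. Serpina3n, an acute-phase inhibitor of serine proteases, rose from 219 ± 154 to 2529 ± 1002 (log2 fold change 3.67, adjusted p = 0.00138). Of 10 Cxcl chemokines, Cxcl5, Cxcl12, Cxcl13, Cxcl14 and Cxcl16 rose (camera adjusted p = 0.000542; adjusted p = 0.880 with an estimated correlation). Cxcl13, which attracts B cells, rose from 8.05 ± 1.93 to 176 ± 83.4 (log2 fold change 4.20, adjusted p = 0.000178), and Cxcl14 from 29.7 ± 18.4 to 685 ± 344 (log2 fold change 4.46, adjusted p = 0.000912). Of 22 C-type lectin genes with the stem Clec 9 rose and 2 fell (camera adjusted p = 0.00105; adjusted p = 0.880 with an estimated correlation). Of 22 Dusp phosphatase genes 6 fell (camera adjusted p = 0.00716; adjusted p = 0.849 with an estimated correlation).

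Among single genes outside the lists, Tppp3, a marker of tendon sheath cells, fell from 336 ± 121 to 12.2 ± 2.41 (log2 fold change -4.63, adjusted p = 5.86e-05), and Gpr165, an orphan receptor, from 17.97 ± 3.598 to 0.243 ± 0.171 (log2 fold change -3.92, adjusted p = 5.86e-05). Pon1, a lipoprotein-associated esterase, fell from 73.5 ± 32.1 to 4.88 ± 4.35 (log2 fold change -3.93, adjusted p = 0.00277). Col6a6, a collagen VI chain, fell from 135 ± 15.9 to 15.1 ± 13.1 (log2 fold change -3.51, adjusted p = 0.00462). Mup2, one of the near-identical major urinary proteins, fell from 30.01 ± 39.6 to 0.574 ± 0.665 (log2 fold change -3.68, adjusted p = 0.00912). In naive replicate 4 it was 89.3, and the log2 fold change without that library was -2.92 (adjusted p = 0.000870). The call of Mup2 was lost without cast replicates 1 and 2 (adjusted p = 0.105) and with DESeq2 on recovered reads.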
